A study of Mus musculus with 4 samples.

How the data were processed

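Epididymal white fat RNA of 4 groups of mice (control, and 1, 3 or 6 days of CL 316243 at 3 nmol/hr, per the labels) was measured on 1 Affymetrix mouse expression array per group. The labels state that the RNA was pooled; the number of mice per pool, the route of dosing, the treatment of the control mice and the collection times are not given in the sources used here. Sample titles write the compound number as 316234 on 2 arrays, and the descriptions of the 3 treated arrays write 316243, which is used here. The deposited values are linear probe set intensities, whole numbers of which between 12.2% and 12.4% per array are at or below 0, as values are after a background or mismatch subtraction. The software, background step and normalization with which the authors made the intensities are not given in the sources used here. The quantiles of the 4 deposited intensity columns were the same within a small margin (medians 314 to 314.5, 75th percentiles 1199 on each array), so the arrays share a distribution before any step taken here.

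Each array of 12488 probe sets holds 66 control probe sets, which were left out of the counts, and 12422 against transcripts. Each array was scaled to a common mean of the values between the 2nd and 98th percentiles, with factors from 0.999 to 1.001. Values were raised to a floor at the 40th percentile of the scaled values (173 intensity units) and put on the log2 scale. A probe set counted as higher or lower when the ratio between 2 arrays was at least 2-fold after the floor. A fold whose dimmer value was at the floor is given as at least that fold. As each group has 1 array, no test was run. Intensities of genes are printed after this scaling and before the floor, rounded to whole numbers.

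Gene symbols came from the array's annotation table. Of the 12422 probe sets, 10833 had 1 symbol, 396 had several and were not named, and 1193 were not listed in the table and were not named here. The symbols stand for 8251 genes, of which 6269 were above the floor on at least 1 array. Entrez identifiers of 10817 probe sets matched the GRCm38.p6 RefSeq gene table, and 0 symbols changed. A gene with several probe sets is represented by the one with the highest mean over the 4 arrays. Other probe sets were compared with it on the days when it passed 2-fold against control. Of the 38 named genes with others, 4 (Atp5g1, Atp5d, Rpl22 and Slpi) had one that went the opposite way. For 12 (Ucp1, Tyms-ps, Atp5d, Slc2a4, Fos, Stmn1, Timp1, Mpeg1, Fcer1g, Ighm, Krt19 and Flt4) another was at or below the floor on both arrays, for Ucp1 at day 6 alone. No genome build is given for the array values, and no coordinates are printed.

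Gene lists were fixed before the data were examined: 18 pathway lists (brown and beige adipocyte genes, fatty acid oxidation, electron transport and ATP synthase, citric acid cycle, fatty acid synthesis, triglyceride synthesis, lipolysis, adipocyte identity, PPAR targets, cAMP and immediate early genes, acute phase and inflammation, interferon response, cell cycle, extracellular matrix, cholesterol synthesis, glycolysis, stress response and ribosomal proteins) and 13 cell type marker lists. A list's value is the median log2 change of its members above the floor on at least 1 array. It was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. A list was described as standing apart when its median lay at or beyond the 2.5 or 97.5 percentile of the random lists.

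The genes named were also set by a rule fixed before the data were examined: for each treated day the 8 largest rises and 8 largest falls among genes whose brighter value was at least 2 times the floor, up to 4 members per list with the largest change past 2-fold, and 10 genes named whatever their values. Of those 10, 8 were measured; Adrb3 and Gk were not analysed here. The rule gave 118 genes, and genes named outside it are said to be so.

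The error of a log2 change was estimated from the difference between 2 probe sets of the same gene, over 512 genes; 3 errors came to 1.79-fold at day 1, 1.59-fold at day 3 and 1.60-fold at day 6. It holds no variation between animals. Between days 3 and 6, 95% of probe sets with a mean of 2 to 4 times the floor lay within 2.14-fold, and 95% of those above 16 times the floor within 1.67-fold. For the overlap of comparisons that share the control array, 100 sets of unchanged arrays were simulated with noise drawn from the day 6 to day 3 differences, which also hold real changes. The method was tested on simulated data for day 1 against control with 12422 probe sets: of 50 probe sets changed by each size, 42% were recovered at 2-fold, 90% at 3-fold and 100% at 4-fold, and 2.79% of 12222 unchanged ones passed 2-fold. That share is near the 337 of 12422 in arrays simulated with day 6 to day 3 noise. The log2 error between probe sets was 0.28 for day 1 against control and 0.21 for day 6 against day 3. The rates may therefore not hold for the measured day 1 array. Alternatives were 3 other scalings, floors at the 25th and 60th percentiles or none, thresholds of 1.5-fold and 3-fold, genes in place of probe sets, the mean of a gene's probe sets, all measured list members, and lists without shared members. Leaving out probe sets whose suffix marks shared or rule-breaking probes was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The tests of dilution of fat cell RNA, of epididymis tissue of one make-up and of noise in the control array used 10000 draws of random genes matched on mean expression in 20 bins; these draws were added after comparisons with 3 measurement errors had been made on the same genes, and their bounds were written before the draws were run.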

Results

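Gene expression was measured on 4 microarrays, each hybridized with RNA pooled from the epididymal white fat of male C57BL/6 mice that were 3 to 4 months old. The control array stood beside arrays from mice given CL 316243, a selective agonist of the β3-adrenergic receptor of fat cells, at 3 nmol/hr for 1, 3 or 6 days. Each group had 1 array and no replicates, so the differences have no replicate check and no p-value is given; the number of arrays limits the precision. The number of mice in each pool is not given in the sources used here. Each array gave values for 12422 probe sets against transcripts, and between 59.9% and 60.2% of them per array lay above the floor of 173 intensity units used here. The value distributions of the 4 arrays were almost identical, so that every change is relative to the common distribution. Probe sets of one gene differed with an error of 0.28 on the log2 scale for day 1 against control, 0.22 for day 3 and 0.23 for day 6, estimated from 512 gene pairs. This error covers the measurement and not the differences between animals or pools.

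The comparison of day 1 with control asks which transcripts had changed after a single day of β3-adrenergic stimulation. Past 2-fold, 30 of 37 inflammatory and 16 of 27 myeloid genes were higher, and 12 of 20 fat cell and 8 of 12 fatty acid synthesis genes were lower. S100a9, a calcium-binding protein abundant in neutrophils, went from 119 to 26727 intensity units and was at least 154-fold higher, and its partner S100a8 was 97.3-fold higher. The cytokine Il1b rose at least 75.8-fold, its natural antagonist Il1rn at least 55.1-fold, and the neutrophil-attracting chemokines Cxcl2 and Cxcl1 at least 55.5-fold and 51.5-fold. Leptin (Lep), the hormone through which fat cells signal energy stores, fell from 18447 to 1607, which is 11.5-fold. In all, 628 probe sets were at least 2-fold higher and 659 at least 2-fold lower at day 1.

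Of the 37 acute phase and inflammatory genes above the floor, 30 rose and 2 fell past 2-fold at day 1, with a median log2 change of 2.33. Saa3, an acute phase protein that fat tissue makes in inflammation, rose from 889 to 19119, or 21.5-fold, and Timp1, an inhibitor of matrix metalloproteinases, rose 16.2-fold. Arg1, an arginase of alternatively activated macrophages, rose at least 83.3-fold, and Chil3, a chitinase-like protein of myeloid cells, at least 37.6-fold. Star, which carries cholesterol into mitochondria for steroid synthesis, stands on the testis and germ cell list and not on the inflammatory one. It rose at least 46.2-fold, from 18 to 7991, and its other probe set went from 177 to 1399. The cAMP and immediate early genes had a median log2 change of 1.10, with 12 of 22 past 2-fold upward and 0 downward. Among them the transcription factor genes Junb, Fosl1 and Fos rose 14.7-fold, at least 8.89-fold and 5.02-fold, and the stress-induced gene Ier3 rose with a log2 change of 3.17. The stress and unfolded protein response genes had a median of 0.59, and 7 of 24 passed 2-fold upward. They included the heme-degrading enzyme Hmox1 at 6.62-fold, the heat shock protein Hsph1 at 3.51-fold and the protein disulfide isomerase Pdia6 at 2.74-fold. For each of these 3 lists, 0 of 10000 random lists of the same size and expression level had a median as high, as a description of these arrays.

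Fat cell genes went the other way at day 1. Of 20 adipocyte identity and adipokine genes, 12 fell and 0 rose past 2-fold, and their median log2 change was -1.15. Pparg, the nuclear receptor that drives fat cell differentiation, fell 3.74-fold, the insulin-responsive glucose transporter Slc2a4 fell 6.25-fold, and neuronatin (Nnat) fell 33.8-fold. Adiponectin (Adipoq), an abundant adipokine, fell from 52042 to 25374, which is 2.05-fold. Of 12 fatty acid synthesis genes, 8 fell and 0 rose, with a median of -1.29. Fatty acid synthase (Fasn) fell 6.39-fold, the lipogenic regulator Thrsp 15.5-fold, the desaturase Scd2 3.51-fold and the elongase Elovl6 3.26-fold. For both lists, 0 of 10000 random lists had a median as low. On the same array the 27 macrophage and myeloid markers had a median of 1.46.

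The lists of mitochondrial fuel oxidation also had medians below 0 at day 1. The fatty acid oxidation list had a median of -0.47, with 5 of 21 genes past 2-fold downward and 1 upward; the dehydrogenase Ivd, which acts on a branched-chain amino acid intermediate, fell 4.98-fold. The upward member was Cpt1a, which controls fatty acid entry into mitochondria and rose from 3334 to 8319. The citric acid cycle and pyruvate dehydrogenase list had a median of -0.55, with Idh2 down 2.14-fold and the pyruvate carboxylase gene Pcx down 2.14-fold, while Pdk4, the kinase that shuts off pyruvate dehydrogenase, rose 3.23-fold. The random lists had medians as low in 86 of 10000 draws for fatty acid oxidation and in 22 for the citric acid cycle. Electron transport and ATP synthase genes had a median of -0.25, with 2 of 55 past 2-fold downward, and the lipolysis list had a median of -0.45, with 2 of 12 past 2-fold downward. Their percentiles among the random lists, 3.46 and 3.33, did not reach the 2.5 at which a list was described as standing apart. The 2 lipolysis genes were Ces1d, a lipid droplet esterase, at 4.59-fold, and G0s2, an inhibitor of adipose triglyceride lipase, at 2.39-fold. Hormone-sensitive lipase (Lipe) went from 15659 to 8425, a log2 change of -0.89.

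PPAR target genes had a median of 0.49 at day 1, and 4 of 13 rose and 1 fell past 2-fold; the thioesterase Acot1 rose at least 5.90-fold. In the triglyceride and lipid droplet list the median was -0.25, with 2 genes up and 2 down of 18. The lipid droplet coat gene Plin2 rose 3.05-fold and the triglyceride-forming enzyme Dgat1 2.61-fold. Of 15 glycolysis genes, 4 rose and 1 fell. The glucose transporter Slc2a1 rose at least 4.15-fold, Slc16a1, which carries lactate, 2.85-fold and the glycolytic enzyme Pgk1 2.78-fold, and the phosphofructokinase Pfkm fell 2.94-fold; the list's median was 0.13. Of 17 interferon response genes, 6 fell and 0 rose, with a median of -0.36 that became -0.69 with the floor at the 25th percentile. The chemokine Cxcl9 fell at least 7.48-fold, the guanylate-binding protein Gbp3 3.67-fold and Ifit3 3.30-fold. Ucp1, the uncoupling protein of brown fat, was below the floor in control and at 3056 at day 1, at least 17.7-fold higher; its other probe set, marked as shared, went from 41 to 553. The brown and beige list as a whole had a median of 0.59 at day 1 over its 6 members above the floor. That median was 0 with the floor at the 25th or 60th percentile, or with all 12 measured members, and Ppargc1a, a coactivator of mitochondrial genes, was below the floor on all 4 arrays.

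**Figure D1:**
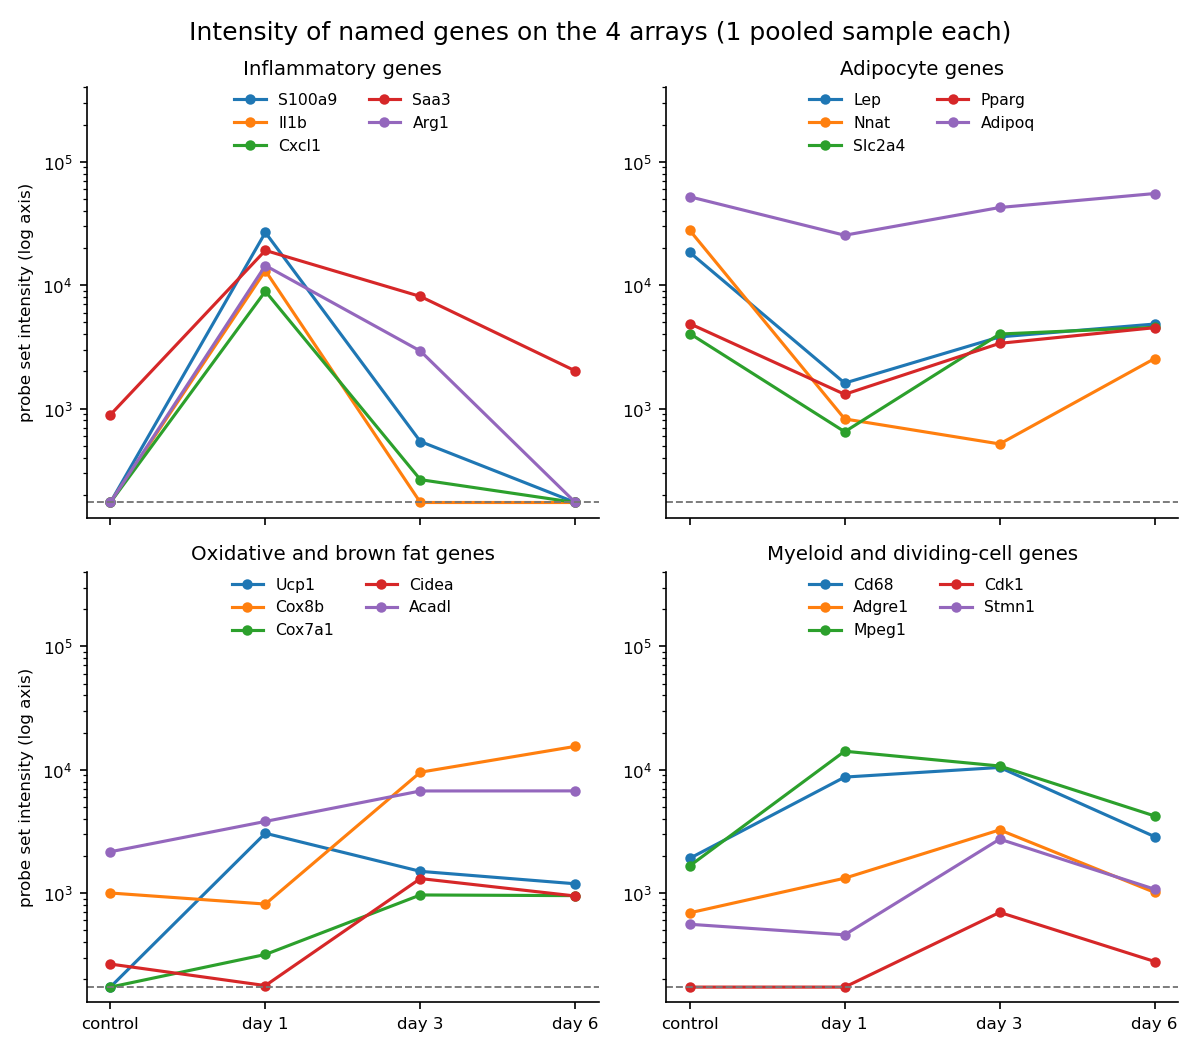
Intensity of 20 genes on the 4 arrays (log axis, intensity units; 1 pooled sample per point, no error bars), drawn at the floor of 173 (dashed line) where lower. Inflammatory genes peak at day 1, with S100a9 at 26727, Pparg, Slc2a4 and Lep are lowest at day 1, and Cox8b reaches 15473 at day 6; Cd68, Adgre1 and the grouping of the panels were chosen after the values were seen.

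The comparison of day 3 with control asks what remained changed or had newly changed under continued treatment. Past 2-fold upward were 5 of 6 brown and beige genes above the floor, 15 of 27 myeloid markers and 10 of 34 cell cycle genes, while 11 of 12 fatty acid synthesis genes were within 2-fold of control. Cox8b, a cytochrome oxidase subunit typical of brown fat and heart, rose from 1002 to 9551, which is 9.54-fold, Cidea, a lipid droplet protein of brown fat, rose 4.93-fold and Ucp1 rose at least 8.68-fold, with its other probe set at 348. Cdk1, the kinase that drives entry into mitosis, rose at least 4.04-fold and the thymidine kinase Tk1 at least 4.31-fold. The other probe set of Tk1 went from 192 to 285. At day 3, 313 probe sets were at least 2-fold higher and 265 at least 2-fold lower.

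Of the 6 brown and beige genes above the floor, 5 rose past 2-fold at day 3, with a median log2 change of 2.39 and 0 of 10000 random lists as high. Cox7a1, another cytochrome oxidase subunit, rose at least 5.59-fold. The median was 1.29 with the floor at the 60th percentile and 0.14 with all 12 measured members, since the other 6 were below the floor on every array. The fatty acid oxidation list had a median of 0.71, with 4 of 21 past 2-fold upward, the long-chain acyl-CoA dehydrogenase Acadl at 3.11-fold and the carnitine carrier Slc25a20 at 2.66-fold among them. Of 55 electron transport and ATP synthase genes, 48 had a log2 change above 0 and 2 passed 2-fold, Cox8b and Cox7a1, which stand on the brown list too; the median was 0.32. The citric acid cycle list had a median of 0.35, with Pdk4 up 3.00-fold and the pyruvate dehydrogenase subunit Dlat up 2.23-fold. For Dlat the other probe set went from 229 to 311. In the triglyceride and lipid droplet list, with a median of 0.22, the fatty acid-binding protein Fabp5 rose 3.67-fold and the fatty acid transport protein Slc27a1 3.40-fold. PPAR target genes had a median of 0.60, with 2 of 13 past 2-fold, and 0.30 with the floor at the 60th percentile or 0.31 without members that stand on another list.

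Of 34 cell cycle and DNA replication genes, 10 rose and 0 fell past 2-fold at day 3, with a median of 0.65 and 0 of 10000 random lists as high. Stmn1, a microtubule regulator of dividing cells, rose 4.90-fold and the mitotic survivin gene Birc5 at least 3.47-fold. Of 27 macrophage and myeloid markers, 15 rose and 0 fell, with a median of 1.13. Acute phase and inflammatory genes had a median of 0.18, with 12 of 37 up and 1 down; the median was 0.47 with the floor at the 25th percentile and 0 with the floor at the 60th. Saa3 was still 9.10-fold, Arg1 at least 16.9-fold, Il1rn at least 9.29-fold, Timp1 6.55-fold and Adam8, a leukocyte metalloprotease, at least 17.6-fold higher than control. Il1b was below the floor on both arrays. The cAMP and immediate early list had a median of 0.18, with 4 of 22 past 2-fold upward, among them Fos at 4.01-fold, and 1 downward.

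Adipocyte identity genes had a median of -0.28 at day 3, with 7 of 20 past 2-fold downward, and -0.53 without members that stand on another list. Nnat fell 54.0-fold, Lep 4.85-fold and the natriuretic peptide clearance receptor Npr3 7.02-fold, while Pparg stood at 3375 against 4874 in control and Slc2a4 at 4015 against 4054. Fatty acid synthesis genes had a median of -0.06, and 1 of 12, Elovl6 at 2.10-fold, passed 2-fold downward. The lipolysis list had a median of 0.00, with 0 of 12 past 2-fold. Interferon response genes had a median of -0.50, with 1 of 17 past 2-fold downward and 0 of 10000 random lists as low. The stress and unfolded protein response list had a median of -0.25, although Hmox1 rose 3.56-fold and the chaperone Dnajb9 2.04-fold.

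The comparison of day 6 with control asks which changes lasted to the end of the treatment. Of 6 brown and beige genes above the floor, 5 were past 2-fold upward, Lep and Nnat were lower, and 3 of 37 inflammatory genes were past 2-fold upward, against 30 at day 1. Cox8b reached 15473, which is 15.4-fold above control, Cox7a1 was at least 5.51-fold, Cidea 3.56-fold and Ucp1 at least 6.88-fold higher by its brighter probe set, while its other probe set was below the floor, at 142, so that their mean log2 change was 1.39. Mmp12, the macrophage metalloelastase, rose 6.54-fold, to 5620. S100a9, Il1b, Arg1 and Chil3 were below the floor again. At day 6, 157 probe sets were at least 2-fold higher and 146 at least 2-fold lower.

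The brown and beige list had a median of 2.15 at day 6. The median was 1.16 with the floor at the 25th percentile, 0.83 with the floor at the 60th and 0 with all 12 measured members. The fatty acid oxidation median was 0.66, with 6 of 21 past 2-fold upward. Acadl rose 3.11-fold and the short-chain dehydrogenase Acads 2.54-fold, while the other probe set of Acads went from 1105 to 1198. Of 55 electron transport and ATP synthase genes, 50 had a log2 change above 0 and 3 passed 2-fold (Cox8b, Cox7a1 and the ATP synthase subunit Atp5d), with a median of 0.38, and the citric acid cycle median was 0.43. For these 4 lists, 0 of 10000 random lists had a median as high. PPAR target genes had a median of 0.49, with 3 of 13 past 2-fold, and Pdk4 rose 3.47-fold. The triglyceride list had a median of 0.21, with Slc27a1 at 3.13-fold and Fabp5 at 2.49-fold. Cell cycle genes had a median of 0.21, which was 0 with the floor at the 60th percentile and 0.41 with the floor at the 25th, and 2 of 34 passed 2-fold upward.

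Adipocyte identity genes had a median of 0.05 at day 6, with 4 of 20 still past 2-fold downward, among them Nnat, at 2542 against 27857 in control, Npr3 at 4.31-fold and Lep at 3.81-fold. Adipoq stood at 55274, Fasn at 32155, Pparg at 4521 and Lipe at 19683, each within 2-fold of control. Fatty acid synthesis genes had a median of -0.06 with 0 of 12 past 2-fold, and lipolysis genes 0.07 with 0 of 12. Acute phase and inflammatory genes had a median of 0.00, with 3 of 37 up and 1 down, and Saa3 remained 2.27-fold higher. The cAMP and immediate early list had a median of -0.17, the interferon list 0.05 and the stress list -0.23. Cholesterol synthesis genes had a median of -0.31, or -0.61 with the floor at the 25th percentile, and the sterol desaturase Sc5d fell 3.79-fold. Other large falls were the muscle actin Acta1 at least 8.62-fold, Cmtm6 5.44-fold, thrombomodulin (Thbd), an anticoagulant receptor, 5.05-fold, and the splicing factor Snrpd3 4.67-fold. The linker histone H1f10 rose 5.63-fold and Tyms-ps, whose probe set is named for a pseudogene of the thymidylate synthase gene, 5.73-fold. Unchanged arrays simulated with the spread between days 3 and 6, which also holds real changes and no variation of the control pool, had on average 337 probe sets past 2-fold, so the day 6 count of 303 is not above that level.

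**Figure D2:**
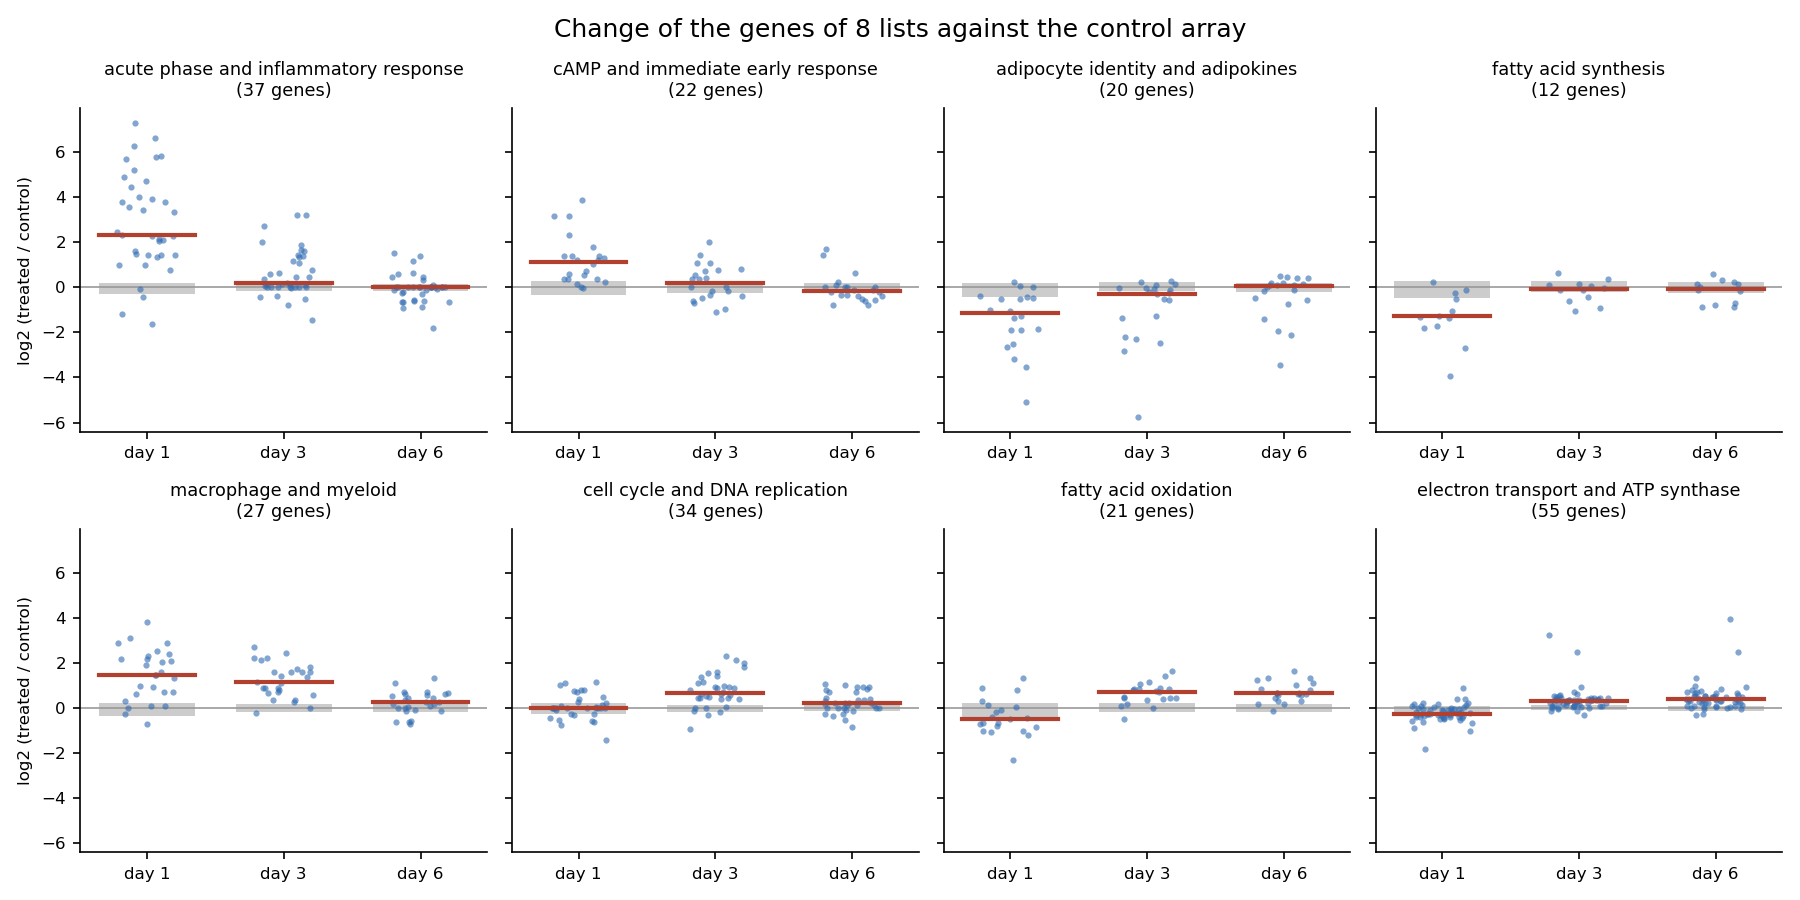
Log2 change against control of the genes of 8 lists at day 1, day 3 and day 6; each point is 1 gene, the red line is the list's median and the grey band holds the central 95% of 10000 random lists. The inflammatory median goes from 2.33 at day 1 to 0.00 at day 6, the fatty acid synthesis median from -1.29 to -0.06, and the fatty acid oxidation median from -0.47 to 0.66.

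Cell type markers were compared on the same arrays. Macrophage and myeloid markers had medians of 1.46, 1.13 and 0.25 on days 1, 3 and 6, with 16 of 27 past 2-fold upward at day 1; 14 members were higher at day 1 than at day 3 and 13 the reverse. Itgam, an integrin of myeloid cells, rose 14.1-fold at day 1 and 4.60-fold at day 3, Mpeg1, a macrophage perforin, 8.51-fold, 6.46-fold and 2.54-fold on days 1, 3 and 6, and the endotoxin coreceptor Cd14 7.41-fold at day 1. Of 2 markers chosen after their values were seen, Cd68 was at 1913 in control and at 8718, 10439 and 2867 on the treated days, and Adgre1, which encodes F4/80, was at 692, 1321, 3254 and 1013. The mast cell and granulocyte list had medians of 0.00, 0.12 and 0.22, with S100a8, S100a9 and the chemokine receptor gene Cxcr2 (at least 8.63-fold) as its 3 rises at day 1; 2 members fell, the neutrophil proteinase Prtn3 at least 4.37-fold and the elastase gene Elane, named after its value was seen, with a log2 change of -1.02. T and NK cell markers, with 5 above the floor, had medians of 0.00 on each day, and the 7 B cell and plasma cell markers -0.36, -0.15 and 0.03. The 3 lymph node and lymphatic markers had medians of -0.52, -0.96 and -0.58, and the day 3 value was 0.035 with the floor at the 25th percentile. The 4 red blood cell markers had medians of -0.35, -0.24 and -0.15.

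Endothelial markers had medians of -0.51, -0.33 and -0.06, with 5 of 16 down at day 1; the tight junction gene Cldn5 fell 4.05-fold at day 1 and 3.81-fold at day 3, while the leukocyte adhesion gene Selp rose at least 6.96-fold at day 1. Stromal and progenitor markers had medians of -0.10, -0.01 and -0.08, with the chemokine Cxcl12 up 3.14-fold and the matrix gene Lum down 3.74-fold at day 1. Smooth muscle markers had medians of -0.34, -0.71 and -0.79, with the smooth muscle myosin Myh11 down 3.38-fold, 2.23-fold and 2.33-fold. Mesothelial markers had medians of -0.39, -0.59 and -0.47, and Upk3b fell 2.35-fold, 2.34-fold and 2.25-fold. Skeletal muscle markers had medians of -0.13, 0.00 and 0.11. The 8 epididymis markers had medians of -1.09, -1.30 and 0.01; without probe sets marked as shared or rule-breaking the first 2 were -2.58 and -2.50. The epididymal glutathione peroxidase Gpx5 was at 6711 in control and at 179, 622 and 302 on the treated days, and the epididymal lipocalin Lcn5 was at 3321, 63, 7 and 8029. Testis and germ cell markers had medians of 0.05, -0.01 and 0.36, and the last was 0 with the floor at the 60th percentile. Of their 6 members above the floor, 1 passed 2-fold upward at day 1, which was Star.

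Of the other lists, extracellular matrix genes had medians of 0.00, 0.00 and -0.20, and the matricellular gene Postn rose 2.12-fold, 3.61-fold and 2.28-fold on days 1, 3 and 6. Cholesterol synthesis genes had medians of 0.11 at day 1 and 0.17 at day 3, and glycolysis genes 0.22 at day 3 and 0.03 at day 6. Cytosolic ribosomal protein genes had medians of 0.11, 0.03 and -0.21. The cell cycle list had a median of 0.00 at day 1. The clock output gene Dbp rose at least 6.40-fold, 8.45-fold and 7.77-fold on days 1, 3 and 6, and the clock repressor Nr1d2 rose 3.48-fold, 3.97-fold and 4.34-fold.

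The treated days were also compared with one another, without the control array. From day 1 to day 3, 452 probe sets were higher and 509 lower past 2-fold; Thrsp went from 2214 to 36861, Cox8b from 815 to 9551 and Slc2a4 from 648 to 4015, while S100a9 went from 26727 to 540 and Il1b from 13108 to 121. From day 3 to day 6, 133 were higher and 226 lower. Arg1 fell at least 16.9-fold over that step, Adam8 6.56-fold, Saa3 4.02-fold, Cd68 3.64-fold, Tk1 3.33-fold and Stmn1 2.55-fold, whereas Mmp12 rose 4.11-fold and Lcn5 at least 46.4-fold. The other probe set of Tk1 did not fall, at 285 on day 3 and 348 on day 6. Between days 1 and 6, 695 were higher and 743 lower at the later day, with Fasn 6.49-fold and Pparg 3.47-fold higher and Junb at least 25.7-fold lower. Each of these counts, and each count against control, changed by more than 1.5-fold with the floor or with the fold threshold.

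**Figure D3:**
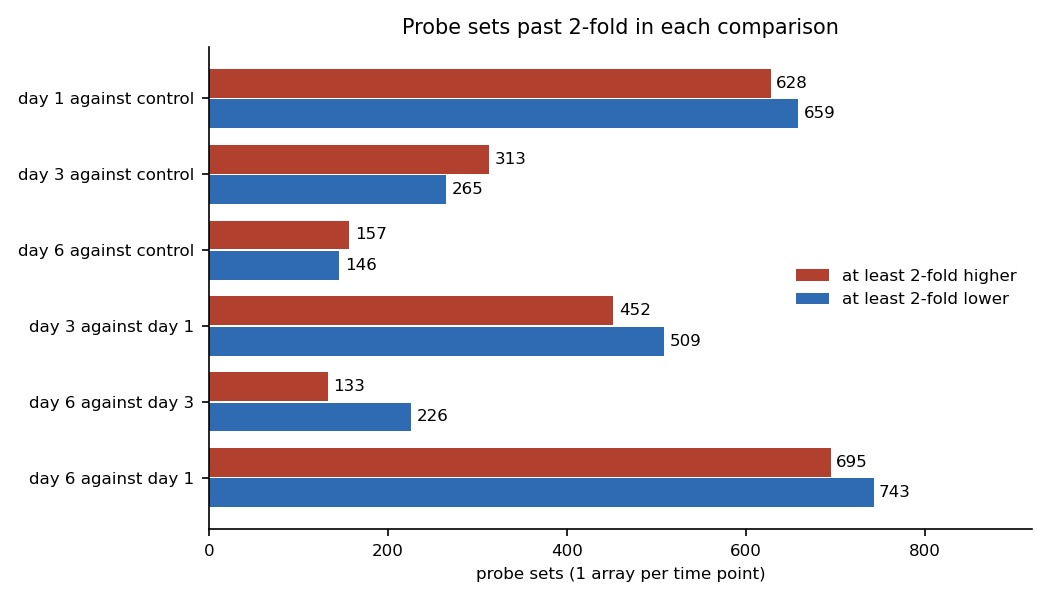
Number of the 12422 probe sets at least 2-fold higher (red) or lower (blue) in each comparison of 2 arrays, counted on an axis that starts at 0. Day 6 against day 1 has the longest bars (695 and 743), and day 6 against control has 157 higher and 146 lower.

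The comparisons with control overlapped. Of 835 probe sets higher on any treated day, 445 were higher only at day 1, 138 at days 1 and 3, 95 only at day 3, 47 at days 3 and 6, 65 only at day 6, 12 at days 1 and 6, and 33 on all 3 days. Of 802 probe sets lower on any day, 483 were lower only at day 1 and 67 on all 3 days. Of the 628 probe sets higher at day 1, 483 (76.9%) were within 1.5-fold of control at day 6, as were 445 (67.5%) of the 659 lower ones. Days 1 and 3 shared 171 higher and 168 lower probe sets, against 15.8 and 14.1 for independent lists and means of 43.9 and 52.1 (at most 57 and 74) for simulated unchanged arrays measured against the same control. Days 3 and 6 shared 80 and 92, against 3.96 and 3.11 for independent lists and means of 44.6 and 52.2 (at most 63 and 78) simulated. Days 1 and 6 shared 45 and 75, against 7.94 and 7.75 for independent lists and means of 44.7 and 52.2 (at most 58 and 79) simulated, so that both lie within the simulated range. All 3 days shared 33 higher probe sets, against 0.200 for independent lists and a mean of 28.5 (at most 41) simulated, and 67 lower ones, against 0.165 and a mean of 34.5 (at most 53). The 33 lie within the simulated range. The simulated noise also holds real changes between days 3 and 6, so a count within its range is not shown to be noise. The simulated arrays had on average 337 probe sets past 2-fold, while days 1, 3 and 6 had 1287, 578 and 303. Longer lists share more probe sets, so counts above or within the simulated range are not compared at equal list size. The covariance of the log2 changes was 0.267 for days 1 and 3 (0.103 simulated), 0.158 for days 3 and 6 (0.104 simulated) and 0.0927 for days 1 and 6 (0.103 simulated), so that the differences were 0.163, 0.054 and -0.011. With a single control array the controls cannot be split, and part of any excess may come from that shared array.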

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

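The tests on the adipocyte genes below were chosen after the result was seen. The fatty acid oxidation list had a median log2 change of -0.47 at day 1 and of 0.71 and 0.66 at days 3 and 6, opposite directions that were noted for a closer look; the difference between the days was not tested, as each day has 1 array. The citric acid cycle and pyruvate dehydrogenase list turned in the same way, from -0.55 to 0.35 and 0.43, and the difference was not tested. The stress and unfolded protein response list turned the other way, from 0.59 to -0.25 and -0.23, and this too was not tested. Single probe sets also crossed control: 16 were at least 2-fold lower at day 1 and at least 2-fold higher at day 6, and 5 did the opposite. The 16 include Eci1 and Slc25a10, a fatty acid oxidation enzyme and the mitochondrial dicarboxylate carrier, and Apoc1, an apolipoprotein; the 5 include Lcn2, a neutrophil lipocalin, the gelatinase Mmp9 and Ifitm6. These genes were chosen after their values were seen, and the differences between days were not tested.

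The comparisons above do not use the 9 probe sets against the control transcripts BioB, BioC, BioDn and CreX. These had a median ratio to control of 1.10 at day 1 (lowest 0.968), 1.26 at day 3 (lowest 0.811) and 1.72 at day 6 (range 1.27 to 2.27). Only at day 6 were all 9 above the control array.

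The fall of adipocyte identity genes at day 1, with a median of -1.15, came with a rise of myeloid markers with a median of 1.46. Dilution of fat cell RNA by RNA of incoming cells that lack the members would lower them by about one factor. Their log2 changes ran from -5.08 to 0.21 with a robust SD of 1.10. As wide a spread was reached by 45 of 10000 random lists of the same size and expression. This argues against dilution by one factor as the whole cause, unless fat cell genes vary more between pools than other genes do. Incoming cells that express some of the members would also widen the spread, so the spread does not decide on dilution by such cells. Other resident cell lists had smaller falls at day 1. Their medians were -0.10 for stromal and progenitor, -0.51 for endothelial, -0.34 for smooth muscle and -0.39 for mesothelial markers. These values differ among themselves and do not decide on a part played by dilution. The comparison with random lists replaced one with 3 measurement errors (0.84), made earlier, because that error holds no variation between pools. Less intact RNA on the day 1 array is argued against by day 6, where the 3' to 5' ratio of the pyruvate carboxylase probe sets was 6.58 (5.58 at day 1, 3.43 in control) while the list's median was 0.05. The same ratio for Actb was 1.34 in control, 1.26 at day 1 and 1.41 at day 6, and for Gapdh 0.94, 0.99 and 0.97. A treatment effect on the fat cells themselves stays open. It cannot be told apart from a change in the cells present, because each array measured RNA of the whole tissue. The median of -1.15 also comes from 1 pooled array.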

How the results depend on the processing

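The leaving out of shared or rule-breaking probe sets was chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The 3 other scalings moved the 876 values computed by at most 0.094 on the log2 scale, so they say little about other normalizations. Probe sets near the floor limit the counts. Of the counts of probe sets, 31 moved by more than 1.5-fold under an alternative and 28 did not. The 3 other scalings gave 6, 6 and 7 of those 28. Counts of probe sets past 2-fold against control on days 1, 3 and 6 were 1287, 578 and 303. They became 1998, 1132 and 847 with the floor at the 25th percentile, 752, 301 and 152 with the floor at the 60th, and 2628, 1804 and 1544 with no floor. They were 2829, 1699 and 1306 at 1.5-fold and 504, 177 and 61 at 3-fold. Day 3 against day 1 (961) gave 1698, 530 and 2324 for the 3 floors and 2506 and 300 for the 2 thresholds; day 6 against day 3 (359) gave 980, 145, 1658, 1276 and 84 in that order, and day 6 against day 1 (1438) gave 2233, 849, 2828, 3159 and 521. The floors and thresholds change these counts by construction. Probe sets shared by all 3 days went from 100 to 60 with the floor at the 60th percentile.

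For lists whose median stood apart from the random lists, 361 values held, 33 moved and 1 reversed. For other lists 435 held and 1 moved. Each of the 3 other scalings, which hardly moved any value, gave 44 of the 361 and 49 of the 435. A move was a shift larger than the distance from the middle to the edge of the random lists' central 95% range. With the floor at the 25th percentile, the lymph node and lymphatic median at day 3 reversed to 0.035, the brown and beige median was 0 at day 1 and 1.16 at day 6, the inflammatory median 2.90 at day 1 and 0.47 at day 3, interferon at day 1 -0.69, cell cycle 0.90 at day 3 and 0.41 at day 6, cholesterol synthesis at day 6 -0.61 and macrophage markers at day 3 1.38. With the floor at the 60th percentile, brown and beige genes had 0, 1.29 and 0.83 on days 1, 3 and 6, fatty acid oxidation 0.48, PPAR targets 0.30, inflammation 0, macrophage 0.89 and smooth muscle -1.02 at day 3, and cell cycle and testis 0 at day 6. With the mean of a gene's probe sets, the values were 0.48 for fatty acid oxidation and 0.90 for macrophage markers at day 3, and 1.61 for brown and beige genes at day 6. With all measured members, brown and beige genes had 0, 0.14 and 0, testis 0 at day 6 and lymph node 0 at day 3, since members below the floor count as 0. Without members on another list, brown and beige genes had 1.48 at day 6, and at day 3 adipocyte identity had -0.53 and PPAR targets 0.31. Without shared or rule-breaking probe sets, inflammation had 2.95 at day 1 and the epididymis list -2.58 and -2.50 at days 1 and 3. For settings other than the floors, thresholds and all measured members, the cause was not tested. T and NK cell and lymph node lists had under 3 members with the floor at the 60th percentile and gave no value. Of the values of named genes, 881 held, 114 moved by more than the robust SD of all changes, and 0 reversed. Each of the 3 other scalings gave 199 of the held values. The floor at the 60th percentile moved 79 and held 120, and the mean of a gene's probe sets moved 35 and held 164.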

Other observations

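The neutrophil gene list and the tests on epididymis genes and on noise in the control array were chosen after the results were seen; the test of clock phase was set before the values it uses were seen. A list of 21 neutrophil genes was written after S100a8 and S100a9 had been seen, and 11 of them were measured. At day 1, 8 of the 11 were at least 2-fold higher, with a median log2 change of 1.95; the median was 0.00 at days 3 and 6. The formyl peptide receptor Fpr2 went from 28 to 1131, the collagenase Mmp8 from 16 to 676, the gelatinase Mmp9 from 353 to 4438 and the surface antigen Ly6g from -8 to 597. By day 3 Mmp9 was at 155 and Ly6g at 47, both below the floor of 173, while the macrophage and myeloid list went from a median of 1.46 at day 1 to 1.13 at day 3. Dio2, the deiodinase that activates thyroid hormone in brown fat, is the fifth brown and beige gene that rose at day 3; it went from 197 to 723, 859 and 433 on days 1, 3 and 6 and was chosen after its values were seen.

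The epididymis adjoins this fat pad. Of 8 genes on its list that were above the floor on at least 1 array, 3 differed between the arrays by large factors. Gpx5 was at 6711, 179, 622 and 302 in control and on days 1, 3 and 6, Lcn5 at 3321, 63, 7 and 8029 and Adam7 at 2654, 200, 251 and 1846. The other 5 had smaller log2 changes than these 3 on days 1 and 3, while at day 6 Cd52 rose by more than Adam7 fell. On days 1, 3 and 6, Clu had -1.44, -1.60 and -0.15 and Adam28 -0.74, -1.01 and -0.34. Ptgds had 0.20, 0.16 and 0.17, Defb1 0.00, 0.00 and 0.24, and Cd52, also a leukocyte gene, 1.58, 0.70 and 1.10. Adam28, Ptgds, Defb1 and Cd52 were chosen after their values were seen. A varying amount of epididymis tissue of one fixed make-up would keep the ratios of Gpx5, Lcn5 and Adam7. The ratio of Lcn5 to Gpx5 went from 0.495 in control to 26.6 at day 6. This log2 shift of 5.75 passes the 0.68 of 3 measurement errors, which argues against one fixed make-up for this pair. As large a shift was reached by 3 of 10000 random gene pairs of like expression. The pair was chosen after its values were seen, so that count decides nothing. A varying amount and segment of epididymis tissue in the pools may still account for the values, and with Adam7 at a log2 change of -0.52 at day 6 no value decides; a treatment effect on these genes was not tested.

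Clock genes were shifted on all 3 treated days: Dbp had log2 changes of 2.68, 3.08 and 2.96 and Nr1d2 of 1.80, 1.99 and 2.12, while Arntl, which peaks at the opposite phase and was chosen after its values were seen, had -2.53, -1.91 and -1.92. Tissue collected at another phase of the day than in control is a candidate explanation, tested on clock genes not looked at before. The 4 that peak with Dbp (Per2, Per3, Nr1d1 and Tef) lay 1.15 above the 3 that peak with Arntl (Clock, Cry1 and Nfil3). This is the difference in median log2 change averaged over the 3 days, past the bound of 0.5 set beforehand. In the order named, the genes' means over the days were 0.39, 0.60, 1.20 and 0.59, and -0.42, -0.38 and -0.21. Single days departed from this: Tef had -0.22 and Nfil3 0.30 at day 1, and Nfil3 0.11 at day 6. Per2 was below the floor in control and at day 3. Noise that strikes genes at random on the single control array is argued against, as 30 of 10000 draws of 4 and 3 other genes of like expression differed by as much; this test replaced an earlier one on Dbp, Nr1d2 and Arntl, which were picked for their shift, and it leaves open a control pool that differs in its clock. Another probe set of Nfil3 had log2 changes of 1.27, -1.27 and -1.27. An effect of the treatment on the clock would shift the same genes and was not tested.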
